A study of Caenorhabditis elegans with 2 samples.

How the data were processed

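Chromatin immunoprecipitation followed by sequencing was performed on whole Caenorhabditis elegans at the L4 larval stage, aged 48 h, in 2 biological replicates. The worms carried a GFP tag in the endogenous pha-4 gene, and chromatin sheared to fragments of 200 to 800 bp was precipitated with an antibody against GFP, per the sample descriptions, while the antibody field of the labels names pha-4. PHA-4 is the FoxA transcription factor required to specify the pharynx, the worm's foregut. Both replicates belonged to 1 group, so no comparison between conditions was possible.

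The authors deposited peak lists on the ce11 assembly, per the file headers. Each replicate had a list of all candidate peaks ranked by the irreproducible discovery rate (IDR) and a thresholded list. Both replicates together had 2 ranked lists, 1 from pooled reads and 1 in which the replicates were ranked against each other, and a thresholded list from each. Per the notes deposited with the lists, each list was made from filtered alignments and a control file. The aligner, the peak caller and their settings were not given in the sources used here. Control reads were not analysed here, so no peak could be compared with the background at its own site. The deposited signal value of a peak is the caller's own and has a scale set per list. It was used to describe and rank peaks within a list, and for correlations across peaks between the replicates and with GC content. The deposited ranked lists also carry the −log10 of the IDR. Every peak of the thresholded lists had a −log10 IDR of at least 2, an IDR of at most 0.01. Read numbers were not given, so the depth of each library is unknown, and intervals on shares cover counting error over peaks or genes only.

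The less strict thresholded list from both replicates served as the main list, with 2947 peaks. Its 27 peaks on the mitochondrial genome were set apart, which left 2920 nuclear peaks. Some peaks share a region, and 2728 summits remained when those within 500 bp of a stronger one were left out. Gene positions came from Ensembl release 115 and sequence from the RefSeq copy of the same assembly, and no peak extended beyond a chromosome end. A gene was counted as having a promoter peak when a summit lay from 1000 bp upstream to 500 bp downstream of its start, and 1 peak could count for neighbouring genes. Of 19973 nuclear protein-coding genes, 1429 (7.15%) had one. Each base was placed in 1 class, with promoters (1000 bp upstream to 200 bp downstream of a gene start) first, then 5′ UTR, coding exon, 3′ UTR, intron, noncoding gene and intergenic sequence. Small noncoding RNA genes were those annotated as tRNA, snoRNA, snRNA, rRNA or miRNA. The plan named noncoding RNA genes without listing the types, and this definition was written once the files were at hand.

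Shares of genes were compared by Fisher's exact test, shares of the genome by an exact binomial test, and motif shares at summits with those in flanking windows by an exact McNemar test against each side, all of them two-sided. The larger of the p-values against the left and right window is given. Motif windows spanned 50 bp to each side of the summit and of points 500 bp away. P-values were adjusted by the Benjamini-Hochberg method over 19 gene lists, 170 gene classes and 12 motifs, with a threshold of 0.05. Gene lists were fixed before the data were examined, as were most tests and alternatives. The comparison of the replicate lists in GC content and coding exons, and the tests of small RNA types other than tRNA, were added after the data had been seen, as were the tests of coding exon peaks in 3 lists. Where clustered copies of a class were counted once, each cluster was represented by its first gene. Where peaks at small noncoding RNA genes were left out, the bases within 250 bp of these genes were left out of the genome shares too. The 19 lists covered pharyngeal muscle, gland and cuticle, foregut, hindgut and intestinal regulators, intestinal terminal genes, autophagy, lysosome and V-ATPase, longevity and stress, ribosomal proteins, nucleolus, body wall muscle, neurons, hypodermis and collagens, germ line, major sperm proteins, histones and housekeeping genes. A gene class was all protein-coding genes sharing the letters before the hyphen of their symbol, with at least 10 members. Intervals are 95% Wilson intervals for shares and exact conditional intervals for odds ratios. Overlap between replicates was set beside 100 random placements of peaks of the same widths on the same chromosomes.

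Genes named in the text were chosen by a rule fixed beforehand: pha-4, the genes nearest to the 25 strongest peaks, up to 4 members per list with the highest promoter signal and up to 4 without a peak, and up to 3 per gene class past the threshold. Because 14 of the 25 strongest peaks were mitochondrial, genes at the 25 strongest nuclear peaks were also eligible, a choice made after the values were seen. Alternatives were the stricter list made from the replicates ranked against each other, the list of each replicate alone, other promoter windows, assignment to the nearest gene start within 2000 bp, random lists matched on distance to the upstream neighbour, other motif windows, and other overlap rules. A looser list with an IDR of 0.05 or less, 1 summit per region, and the removal of peaks within 250 bp of small noncoding RNA genes were added after seeing the data.

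The tests were checked on simulated data. With 10 of 170 gene classes given promoter peaks at 40% of their members and other genes at 7%, all 10 were recovered. As having peaks more often, 0 others were called. Calls of peaks less often were not counted in this check. With the motif planted in 18.3% of 2920 random windows, an excess of 13.4 percentage points (95% interval 11.3 to 15.6) was measured where 13.6 was planted. The planted classes were drawn from the larger ones only, and no smaller motif share was planted. Power for small lists, small classes and small motif excesses was therefore not checked. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.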

Results

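PHA-4 binding was profiled in L4 larvae of a strain with a GFP tag at the endogenous pha-4 gene, in 2 biological replicates of whole worms. The thresholded list of replicate 1 held 2114 nuclear peaks and that of replicate 2 held 1643. The main list, made from both, held 2920 nuclear peaks with a median width of 340 bp. Read depth was unknown.

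The first question was how far the replicates called the same sites. Of the 1643 replicate 2 peaks, 875 (53.3%, 95% Wilson interval 50.8 to 55.7) overlapped a replicate 1 peak by at least 1 bp, against 1.30% on average for randomly placed peaks and 2.13% in the highest of 100 placements. Of the 2114 replicate 1 peaks, 853 (40.4%, 38.3 to 42.5) overlapped a replicate 2 peak. Among the 100 strongest peaks of each list, 98 of replicate 1 were also in the replicate 2 list, and 68 of replicate 2 were in the replicate 1 list. Across the 72493 nuclear peaks ranked between the replicates, the signal values had a Pearson r of 0.521 and a Spearman rho of 0.232, a correlation across peaks, which are not independent replicates. Of the 2920 main-list peaks, 854 (29.2%) overlapped both replicate lists, 980 only that of replicate 1, 418 only that of replicate 2, and 668 neither.

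The replicates differed in where their peaks lay, a comparison that was not planned and was made after the lists had been seen. Coding exons held 169 of the 1643 replicate 2 summits (10.3%, 95% Wilson interval 8.91 to 11.8) and 83 of the 2114 replicate 1 summits (3.93%, 3.18 to 4.84), an odds ratio of 2.81 (95% interval 2.12 to 3.73, Fisher's exact p = 1.47e-14). The GC content within 100 bp of the summit averaged 49.003% ± 8.20 (SD over 1643 peaks) in replicate 2 and 42.1% ± 7.45 (SD over 2114 peaks) in replicate 1. These tests compare 1 list with another and treat peaks as units.

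Main-list summits were concentrated in promoters and depleted from coding exons. Promoters held 1143 of the 2920 summits (39.1%, 95% Wilson interval 37.4 to 40.9), against 21.5% of the nuclear genome (exact binomial p = 1.02e-103). Coding exons held 6.13% of summits against 19.8% of the genome (exact binomial p = 8.54e-98), and introns 24.97% against 30.5% (p = 3.16e-11). Noncoding genes held 6.13% against 3.44% (exact binomial p = 5.38e-13), and away from small noncoding RNA genes they held 2.32% of summits against 3.40% of the remaining genome (p = 0.00282).

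By chromosome, genes on III and I most often had a promoter peak, at 10.4% (95% Wilson interval 9.31 to 11.6) and 9.83% (8.80 to 11.0), and genes on V least often, at 4.79% (4.23 to 5.41). On X, 166 of 2731 genes (6.08%) had a promoter peak, against 1263 of 17242 autosomal genes (7.33%), an odds ratio of 0.819 (95% interval 0.689 to 0.969, Fisher's exact p = 0.0184). This difference was lost in the stricter list (odds ratio 0.881, Fisher's exact p = 0.256) and in the list of replicate 2 alone (0.953, p = 0.708).

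The 2 strongest nuclear peaks were intergenic, with signal values of 1253 on chromosome V (summit 13646105) and 1092 on chromosome II (summit 2974147). The peak at rpl-3, a protein of the large ribosomal subunit, had a signal value of 1029 and its summit on chromosome III at 3867576, 278 bp upstream of the gene start. A peak 148 bp upstream of F44E5.4, a gene of the HSP70 chaperone family, had a signal value of 998 (chromosome II, summit 11759459). Others of the 25 strongest lay at rpl-15 (695.7), rpl-35 (609.7), drr-2 (581.2), the p97 ATPase gene cdc-48.1 (564.7), the cytochrome c oxidase subunit gene cox-5A (537.9) and the splicing helicase gene mog-4 (535.3). Of these 25 nuclear peaks, 4 lay at a ribosomal protein gene and 6 within 250 bp of a small noncoding RNA gene. The peak at the innexin gene inx-18 (786.5) was in the replicate 2 list and not in that of replicate 1.

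At pha-4 itself (WBGene00004013, chromosome V, 20753052 to 20760317, plus strand), the main list held 2 intronic peaks. Their summits lay 722 and 2603 bp downstream of the gene start, with signal values of 67.1 and 57.0, in the lower part of the list: 10.4% and 6.58% of nuclear peaks were weaker. The first was in neither replicate list and the second in that of replicate 1. Neither summit fell in the promoter window.

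The lists fixed for the foregut asked whether genes chosen for the organ that PHA-4 specifies had promoter peaks. Their expression in the pharynx was not checked. No excess of promoter peaks was detected at any of the 4 lists. Of the 13 pharyngeal muscle genes, 1 had a promoter peak, eat-18 (signal 110.0), and myo-1 and myo-2, which encode pharyngeal myosins, had none. The pharyngeal cuticle list had 1 of 13, idpc-1 (53.7), and abu-1 and abu-6 had none. The muscle and cuticle lists both had 0 of 13 in the stricter list and in that of replicate 1 alone. Each had 1 of 13 in the list of replicate 2 alone. The pharyngeal gland list had 0 of 11, which allows a share of up to 25.9% (upper Wilson limit), with hlh-6 and phat-1 among those without a peak. The foregut regulators had 0 of 18 (up to 17.6%), with pha-1, pha-2 and ceh-22 among them. This list also held pha-4 itself, whose main-list peaks lay outside the promoter window, and genes such as lin-12, glp-1 and daf-12. With peaks given to the nearest gene the foregut regulators had 3 of 18 (odds ratio 2.26, Fisher's exact test, adjusted p = 0.305), and in the list of replicate 2 alone 1 of 18 (1.47, adjusted p = 0.688). All 4 adjusted p-values in the main list were 1, and with 11 to 18 genes a list a moderate excess was not detectable.

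Intestinal and hindgut lists did not pass the threshold. Of 34 intestinal terminal genes, 5 (14.7%, 95% Wilson interval 6.45 to 30.1) had a promoter peak against 7.14% of other genes (odds ratio 2.24, Fisher's exact test, adjusted p = 0.219). The strongest were cav-2 (signal 146.2), the peptide transporter gene pept-1 (98.7), the yolk protein gene vit-6 (93.5) and cpr-4 (91.9). In the stricter list the list passed (odds ratio 3.9996, adjusted p = 0.0395, Fisher's exact test), as it did in 3 of the other alternatives, and in the list of replicate 2 alone it was 0.756. Of 14 intestinal regulators, 1 had a peak, nhr-49 (183.5), a regulator of fat metabolism, while elt-2, the main intestinal GATA factor, had none (odds ratio 0.998, Fisher's exact test, adjusted p = 1). With peaks given to the nearest gene this list had 4 of 14 (odds ratio 4.52, Fisher's exact test, adjusted p = 0.0715), and in the list of replicate 1 alone 2 of 14 (2.85, adjusted p = 0.379). None of the 12 hindgut and excretory regulators had one (up to 24.2%, Fisher's exact test, adjusted p = 1).

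Ribosomal protein genes and housekeeping genes had promoter peaks far more often than other genes. Of 79 ribosomal protein genes, 43 (54.4%, 95% Wilson interval 43.5 to 65.0) had one, against 6.97% of other genes (odds ratio 15.95, 95% interval 9.96 to 25.6, Fisher's exact test, adjusted p = 1.85e-27). The housekeeping list had 12 of 21 (57.1%, odds ratio 17.4, 6.73 to 46.9, Fisher's exact test, adjusted p = 2.62e-08), led by the translation factor genes eif-3.C (signal 295.5) and eef-1A.2 (262.8), the tubulin gene tba-2 (231.5) and eef-1A.1 (165.4). Histone genes had 16 of 72 (22.2%, odds ratio 3.74, 2.00 to 6.63, Fisher's exact test, adjusted p = 0.000245), among them his-37 (414.7) and the divergent pair his-5 and his-6, which share 1 peak (240.8). The histone call ended with peaks given to the nearest gene (Fisher's exact test, adjusted p = 0.173) and with the narrow promoter window (0.0904). Histone genes have near-identical clustered copies, and with copies within 20 kb counted once the his class had the same odds ratio of 3.74 on fewer genes and did not pass (Fisher's exact test, adjusted p = 0.349).

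Autophagy genes and proton pump genes of the V-ATPase also had promoter peaks more often. Of 26 autophagy genes, 7 (26.9%, 95% Wilson interval 13.7 to 46.1) had a promoter peak (odds ratio 4.80, 95% interval 1.70 to 11.9, Fisher's exact test, adjusted p = 0.00705): epg-8 (signal 177.5), the Atg8 homologues lgg-2 (172.4) and lgg-1 (146.1), and atg-9 (127.3) were the strongest, and unc-51 and atg-13 had none. Of 34 lysosome and V-ATPase genes, 9 (26.5%, 14.6 to 43.1) had one (odds ratio 4.69, 1.92 to 10.4, Fisher's exact test, adjusted p = 0.00232), led by the proton pump subunit genes vha-8 (170.7), vha-12 (156.3) and vha-1 (119.8). All 9 were among the 20 vha genes, and the 14 other lysosome genes had 0 (up to 21.5%). The autophagy call was lost in the list of replicate 2 alone (Fisher's exact test, adjusted p = 0.670) and the lysosome and V-ATPase call in the list of replicate 1 alone (0.276). With the narrow window the latter was also lost (0.0904).

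The remaining lists did not pass. The nucleolus list had 4 of 18, led by pro-1 (signal 222.5, Fisher's exact test, adjusted p = 0.113), and longevity and stress 5 of 29 (0.143), led by the chaperone gene hsp-60 (506.6), while sod-1 and sod-2 had none. Both passed in the looser list (Fisher's exact test, adjusted p = 0.0206 and 0.00208), and longevity and stress also with the widest window (0.0464). Germ line genes had 4 of 38 (0.599), body wall muscle 1 of 29 (pat-4, 85.7), and pan-neuronal genes 1 of 26 (ida-1, 110.9), both with an adjusted p of 1. The pan-neuronal odds ratio turned from 0.519 to 4.56 in the list of replicate 2 alone (4 of 26, Fisher's exact test, adjusted p = 0.0631). The collagen and hypodermis list had 0 of 36 (up to 9.64%, Fisher's exact test, adjusted p = 0.231) and the major sperm proteins 0 of 31 (up to 11.0%, 0.317).

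**Figure D1:**
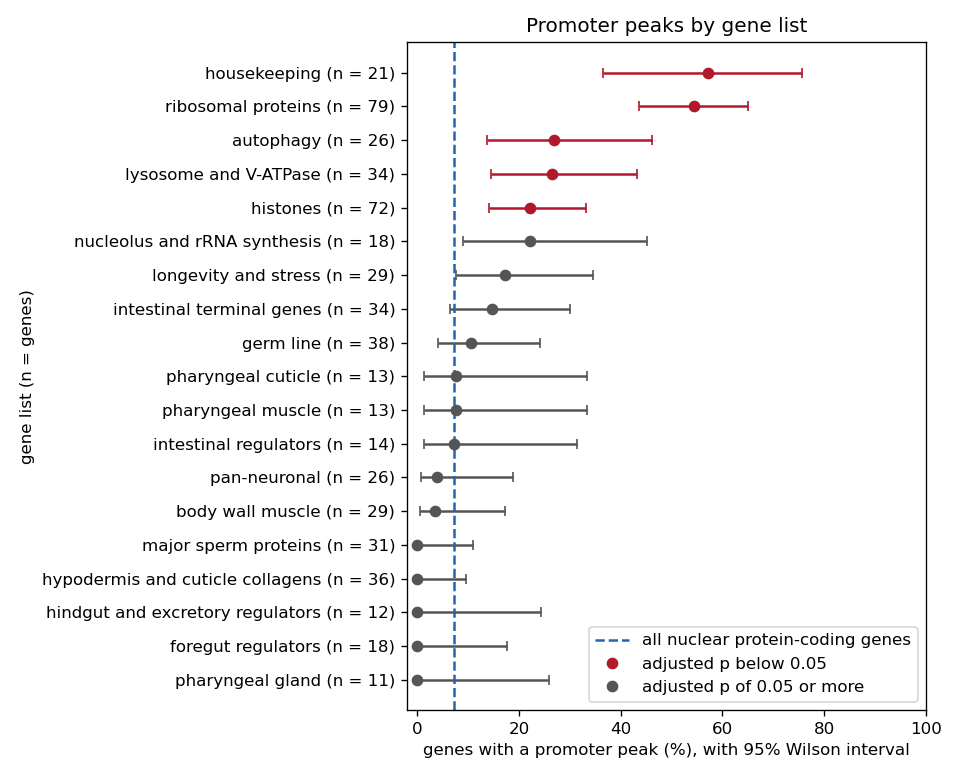
Share of the genes in each of 19 lists with a promoter peak in the main list (x axis, percent, points with 95% Wilson intervals); the dashed line marks the 7.15% of all nuclear protein-coding genes. Ribosomal protein genes (54.4%) and housekeeping genes (57.1%) lie far to the right of it, and the pharyngeal lists do not.

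A search over 170 gene classes found 14 past the threshold, 9 with promoter peaks more often than other genes and 5 less often (Fisher's exact test throughout). Those with peaks more often included rps with 20 of 31 members (Fisher's exact test, adjusted p = 7.31e-14), rpl with 22 of 45 (3.82e-12), the V-ATPase class vha with 9 of 20 (1.33e-04), the heat shock class hsp with 8 of 22 (0.00211) and the vacuolar sorting class vps with 9 of 31 (0.00485). The vha call was lost in the list of replicate 1 alone (Fisher's exact test, adjusted p = 0.235) and with the narrow window (0.0529), and the vps call in the list of replicate 2 alone (0.0875), with the narrow window (0.0695) and with the nearest gene (0.115). The lin class, genes named for cell lineage defects, had 14 of 45 (7.44e-05), with lin-54 (signal 425.0), lin-9 (286.9) and lin-53 (247.2) the strongest. The lin-54 peak was shared with rpl-12. The classes with peaks less often were the chemoreceptor classes str (0 of 193, Fisher's exact test, adjusted p = 4.85e-05), srw (0 of 109, 0.0104), srx (no member, 0.0205) and srh (5 of 220, 0.0283), and the C-type lectin class clec (6 of 240, 0.0283). Chemoreceptor genes lie in clusters, and with copies within 20 kb counted once str remained past the threshold and srw, srx, srh and clec did not, with odds ratios of 0 for srw and srx as before. The srw, srx and srh calls were also lost in the stricter list, in the list of either replicate alone and with the narrow window, and the clec call in the list of replicate 2 alone and with the narrow window.

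Most tRNA genes lay close to a summit. Of 612 nuclear tRNA genes, 403 (65.8%, 95% Wilson interval 62.004 to 69.5) lay within 250 bp of a summit, against 698 of 19973 protein-coding gene starts (3.49%), an odds ratio of 53.2 (95% interval 44.2 to 64.3, Fisher's exact test). The odds ratio was 29.5 in the list of replicate 2 alone and 72.3 in that of replicate 1 alone, and it ranged from 36.2 within 500 bp to 111.4 within 100 bp. The other small RNA types were tested only after the tRNA result was seen. Of 346 snoRNA genes, 94 (27.2%, odds ratio 10.3, Fisher's exact test, adjusted p = 1.92e-52) did, as did 30 of 129 snRNA genes (23.3%, odds ratio 8.37, adjusted p = 3.68e-16). miRNA genes did not differ detectably from coding starts (13 of 261, Fisher's exact test, adjusted p = 0.222), and 0 of 20 rRNA genes lay near a summit. Together, 511 nuclear peaks (17.5%) lay within 250 bp of a small noncoding RNA gene. Many tRNA genes have near-identical copies, and how the authors placed reads among them was not given.

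Peaks at small noncoding RNA genes were more frequent among strong peaks than among weak ones. They made up 34.2% (95% Wilson interval 30.9 to 37.8) of the strongest 730 nuclear peaks and 4.79% (3.47 to 6.59) of the weakest 730 (Fisher's exact test, adjusted p = 2.83e-49). The difference of 29.5 percentage points was 6.05 in the list of replicate 2 alone (Fisher's exact test, adjusted p = 0.0440). The promoter share was 42.2% in the strongest group and 31.6% in the weakest (Fisher's exact test, adjusted p = 5.52e-05), a difference that was not past the threshold in the stricter list (adjusted p = 0.102). The forkhead consensus share was 22.3% and 25.5% (Fisher's exact test, adjusted p = 0.177). It was lower in the strongest peaks with 3 signal groups in place of 4 (Fisher's exact test, adjusted p = 0.00561) and in the looser list (0.00288). The consensus lay at 25.6% of the 2409 peaks away from small noncoding RNA genes, against 24.3% of all 2920. Peaks at these genes thus had it less often, and their frequency among strong peaks could lower its share there. The signal groups were not compared without them. Of the 854 peaks in both replicate lists, 28.5% lay at small noncoding RNA genes, against 13.0% of the other 2066 (Fisher's exact test, adjusted p = 1.28e-21). Promoter shares were 42.04% and 37.9% (Fisher's exact test, adjusted p = 0.0618), a difference past the threshold with 1 summit per region (adjusted p = 0.0481) and in the looser list (1.72e-05). Forkhead consensus shares were 24.4% and 24.3% (Fisher's exact test, adjusted p = 1).

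**Figure D2:**
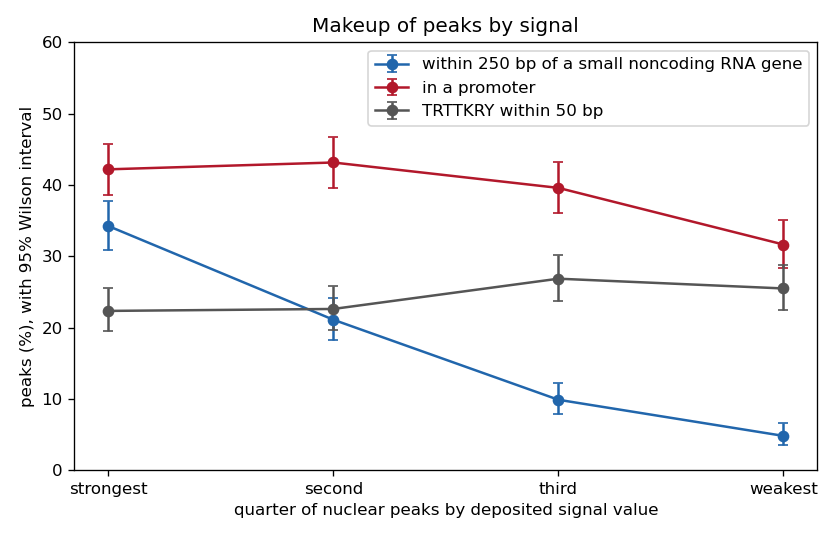
Makeup of the 2920 nuclear peaks by signal, in 4 groups of 730 from strongest to weakest (x axis); the y axis is the percent of peaks, with 95% Wilson intervals. The share at small noncoding RNA genes falls from 34.2% to 4.79%, and that with the forkhead consensus runs from 22.3% to 25.5%.

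The published PHA-4 consensus TRTTKRY was not more frequent at summits than beside them. It lay within 50 bp of 710 of 2920 summits (24.3%), against 25.5% of the flanking windows, a difference of -1.20 percentage points (95% interval -3.09 to 0.696, exact McNemar p = 0.313). The reversed pattern YRKTTRT, a control for base composition, gave 20.7% against 23.2%. In the list of replicate 2 alone both patterns were scarcer at summits, by 8.09 points for TRTTKRY (exact McNemar p = 3.50e-07) and 7.21 points for YRKTTRT. The GATA motif WGATAR gave 18.9% against 19.6% (exact McNemar p = 0.507). It was scarcer at summits in the list of replicate 2 alone (-6.06 points, exact McNemar p = 0.000103) and in the stricter list (-3.12 points, p = 0.0309).

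Specific forkhead sequences were more frequent at summits by small amounts. TGTTTAC lay at 2.05% of summits against 1.10% of flanks (exact McNemar test, adjusted p = 0.0122) and TGTTTGC at 3.42% against 1.97% (adjusted p = 0.00796). The TGTTTAC excess was not past the threshold in the stricter list (0.868 points against 0.959 in the main list, exact McNemar test, adjusted p = 0.201), in the lists of replicate 2 and replicate 1 alone (0.524 and 0.248), or away from small noncoding RNA genes (0.196). TGTTTGC remained past it in these lists, but not in that of replicate 2 alone (exact McNemar test, adjusted p = 0.419). GAGAGA had the largest excess of the 12 motifs, 17.7% against 5.99% (exact McNemar test, adjusted p = 5.89e-40). Its excess of 11.7 points was 20.3 in the list of replicate 2 alone and 10.6 in that of replicate 1 alone. The E-box CACGTG (4.11% against 2.11%, exact McNemar test, adjusted p = 0.000207), CAGCTG (3.87% against 2.26%, 0.00339) and GGGGGG (4.49% against 1.49%, 1.19e-08) were also more frequent. CACGTG was not past the threshold in the list of replicate 2 alone (exact McNemar test, adjusted p = 0.233), nor CAGCTG in that of replicate 1 alone (0.347) or in the stricter list (0.0503). In the stricter list the CAGCTG excess was 1.70 points, against 1.61 in the main list. TGATAA and TTGCGCAA did not pass (exact McNemar test, adjusted p = 0.694 and 0.739). In the list of replicate 2 alone TGATAA was scarcer at summits, 4.38% against 8.25% (exact McNemar test, adjusted p = 2.41e-05).

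**Figure D3:**
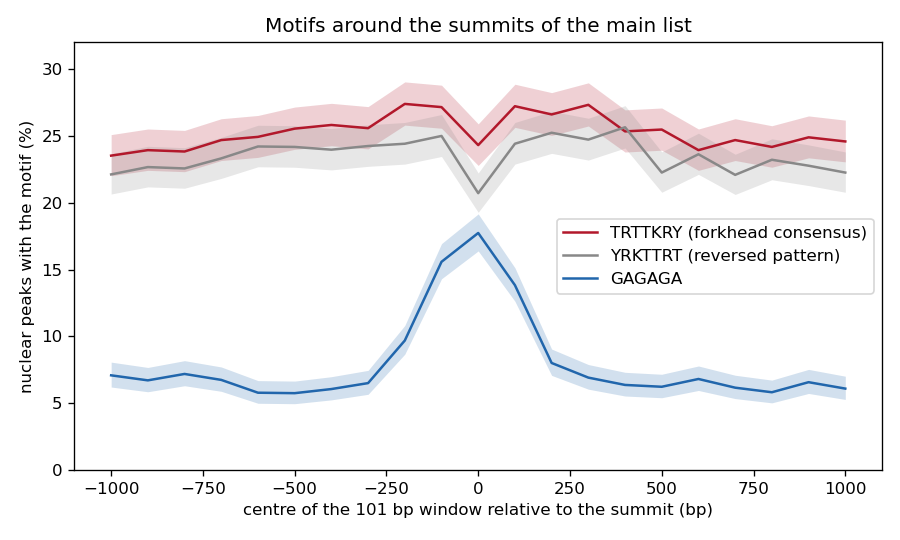
Percent of nuclear main-list peaks with a motif within 50 bp (y axis) of each position, by its distance from the summit in bp (x axis), with 95% Wilson intervals shaded. GAGAGA rises to 17.7% at the summit, while TRTTKRY is at 24.3% there and its reversed pattern YRKTTRT at 20.7%.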

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

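Of the tests below, those of mitochondrial coverage, of the housekeeping list, of coding exons in 3 lists, of the reversed pattern and TGTTTAC at small noncoding RNA and ribosomal protein genes, and of signal against GC content were chosen only after the result was seen, the last as the third version after one with mislabelled columns and one on all main-list peaks. No control data were analysed here and the design has 1 group, so no biological explanation was tested against another condition.

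The 27 mitochondrial peaks of the main list stood outside every comparison above and carried its strongest signal. They made up 14 of the 25 strongest peaks, with signal values up to 6282 against 1253 for the strongest nuclear peak. These 14 were summits within shared long intervals, from 1 to 8568 or from 8546 to 13403, and not separate regions. The 27 peaks covered 98.4% of the 13794 bp of the mitochondrial genome, as an excess of mitochondrial reads over the whole molecule would give. The share of their summits with TRTTKRY within 50 bp was 66.7%, equal to the 95th percentile of random mitochondrial positions and above their median of 51.9%, so motif binding was neither supported nor excluded.

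Strong nuclear peaks lay at small noncoding RNA and ribosomal protein genes. The forkhead test took the 522 peaks within 250 bp of a small noncoding RNA gene or a ribosomal protein gene start. Of these, 511 lay at small noncoding RNA genes, so ribosomal protein genes were hardly covered. The rpl-3, rpl-15 and rpl-35 summits lay farther out. TRTTKRY was less frequent at these 522 summits than in the flanks, a difference of -6.42 percentage points (95% interval -10.6 to -2.26). Its reversed pattern was at 23.2% against 23.5%. At other nuclear peaks the differences were -0.0626 and -2.98 points. The core sequence TGTTTAC went the other way at the 522 peaks, 3.45% against 1.05% (exact McNemar test, adjusted p = 0.151). An excess of TRTTKRY is thus argued against at small noncoding RNA genes. Binding stays undecided, since tRNA sequence (GTTCGA at 41.7% of the 511 summits) also sets motif shares. High transcription in any tissue was tested at promoters with 3 lists, of body wall muscle, collagen and sperm protein genes. Of these, 0 had more promoter peaks than other genes, and the upper 95% limits of their odds ratios were 2.81, 1.40 and 1.64. An excess like that of ribosomal protein genes is argued against for these lists. Transcription was not measured, so smaller effects and other tissues stay open, and only promoters entered the bound set beforehand. In coding exons, which it left out, peaks lay in 1 of 36 collagen and hypodermis genes in the main list, 3 in replicate 2 and 0 in replicate 1 (Fisher's exact test, adjusted p = 0.767, 0.00728 and 1), and in 0 genes of the other lists. Signal at genes transcribed in most cells stays open: the housekeeping list had an odds ratio of 17.4, and from 11.6 to 19.1 over the alternatives.

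Replicate 2 peaks were richer in GC and in coding exons. Signal in coding exons alone does not account for this: outside them, mean GC was 10.9 percentage points higher at peaks only replicate 2 called (50.7% ± 8.88, SD over 367 peaks) than at those only replicate 1 called (39.8% ± 6.64). A GC bias of the replicate 2 library is a candidate explanation. Across 841 main-list peaks outside coding exons that overlapped both replicate lists, the Spearman rho of signal with GC was 0.356 in replicate 2 and -0.0407 in replicate 1, a difference of 0.396 (95% bootstrap interval 0.330 to 0.465), against 0.502 over the 2585 main-list peaks outside coding exons with a peak in both ranked lists, a set chosen in part by the pattern itself. A difference between the worms of the replicates could give the same and stays open.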

How the results depend on the processing

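The looser list, 1 summit per region, removal of peaks at small noncoding RNA genes, and all alternatives for the other motifs were chosen after seeing the data, as were those for the exon, intron and noncoding gene shares. Without peaks at small noncoding RNA genes the noncoding gene share turned from above to below that of the remaining genome (2.32%). The TGATAA difference ran from -3.86 to 0.355 points with 1 replicate left out and turned direction in the list of replicate 2 alone. The promoter share stayed above the genome share throughout. It was 29.3% against 11.2% of the genome with the narrow window and 53.3% against 39.9% with the widest. The ribosomal protein and housekeeping lists passed in all 9 settings run for each list, as they did against matched random lists. Replicate overlap was 40.5% with 50% reciprocal overlap, 47.7% with summits within 100 bp and 50.8% with equal numbers of peaks. In the stricter list the X odds ratio was 0.881, the GATA difference -3.12 points and the promoter difference between strongest and weakest peaks 6.59 points. With 1 replicate left out the X odds ratio ran from 0.767 to 0.953, the forkhead difference from -8.09 to -0.331 points, the GATA difference from -6.06 to -1.11 points, and the other motifs called in excess from 3 to 4, against 6; gene classes numbered 8 without either, against 14, and these 8 were among the 14 each time. The looser list called 8 gene lists and 23 classes, against 5 and 14, gave -5.16 points for the forkhead consensus in the strongest against the weakest peaks and 7.92 points for promoters in peaks of both replicates. With 3 signal groups in place of 4 the former was -5.37 points and with 1 summit per region the latter was 4.49 points. The narrow promoter window called 3 lists and 6 classes, and counting clustered copies once left 9 classes, where fewer members enter. Otherwise the cause was not tested. Read depth was unknown, and lists of 11 to 18 genes limit what could be detected. No paired analysis was possible because the series has 1 group.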

Other observations

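Of the tests in this part, those of base composition and of the replicate 1 list were chosen only after the result was seen, as was the sequence search.

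A search of all 2080 six-base sequences named those with the largest excess at summits. Away from small noncoding RNA genes (2409 peaks), GAGAGA lay at 19.7% of summits against 5.98% of flanks, CGTCTC at 13.9% against 3.69%, and ACGCAG at 12.2% against 2.22%, with adjusted p-values of 2.22e-39, 1.98e-31 and 1.17e-34 (exact McNemar test). At the 511 peaks by small noncoding RNA genes, GTTCGA, part of the internal B box of tRNA promoters, lay at 41.7% of summits against 4.70% of flanks (exact McNemar test, adjusted p = 1.10e-39).

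Peaks of the replicate 2 list that overlapped no replicate 1 peak, in the main list or not, had their summits in coding exons of 130 genes, of which 25 (19.2%) were col collagen genes, a class with 156 of 19973 nuclear protein-coding genes (0.781%). The strongest, named here after their values were seen, were in grl-25 (519.3), col-50 (508.0) and col-51 (365.0). Main-list peaks that only replicate 2 called averaged 51.7% GC, against 39.9% for those only replicate 1 called. The share of all genes takes no account of this. The GC content of collagen exons was not measured, so an excess particular to collagen genes was not tested.

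One hypothesis was that foregut genes carry signal below the threshold. In the pooled ranked list, 1 of the 4 foregut lists had a median strongest promoter signal above the upper limit of the 95% range of 10000 random lists matched on upstream distance. This was the pharyngeal cuticle list, at 98.4, and pharyngeal muscle, pharyngeal gland and foregut regulators were at 24.1, 26.7 and 33.9. The intestinal terminal genes were at 99.99, the intestinal regulators at 98.7, and the hindgut and excretory regulators at 13.8. The median signal was 0 for pharyngeal muscle, pharyngeal gland and the hindgut and excretory regulators. For pharyngeal gland the median of the random lists was 0 too. At this floor a percentile does not rank weak signal. However, 10 of the 19 lists passed that limit, pan-neuronal genes (99.6) among them, so a high percentile was not particular to the digestive tract. The test leaves the hypothesis undecided.

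It was also asked whether GC-rich summits hide the AT-rich consensus. The excess of TRTTKRY over its flanks was 1.30 percentage points higher than that of its reversed pattern (95% interval -0.806 to 3.41). This excludes a hidden excess of 5 points or more only for the 2920 nuclear peaks as a single set. At the 522 peaks by small noncoding RNA or ribosomal protein genes the contrast was -6.13 points (-11.6 to -0.651). At the other 2398 peaks it was 2.92 points (0.652 to 5.19), with TRTTKRY itself at -0.0626 points against its flanks. A hidden excess, even of 5 points, is therefore not excluded at these 2398 peaks. Peaks of replicate 2 did not hide an excess of 5 points in the replicate 1 list. There the excess of TRTTKRY over its flanks was -0.331 points (-2.60 to 1.93). That list includes peaks shared with replicate 2. Within the main list, TRTTKRY was at 26.5% of summits against 24.4% of flanks in peaks only replicate 1 called. It was at 14.8% against 25.2% where only replicate 2 called them. In peaks of both lists it was at 24.4% against 25.1%, and in peaks of neither at 26.9% against 27.8%.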
